A study of Mus musculus with 2 samples.

How the data were processed

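Orthotopic KPC mouse pancreatic tumors treated with vehicle (DMSO) or with EIPA at 10 mg/kg, an inhibitor of macropinocytosis, were profiled by probe-based single-cell RNA sequencing. Per the labels' protocols, each of the 2 samples was made from 4 pooled tumors. The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 8.0.0 against mm10, per the submitters' processing notes and the matrix header. Both samples share 1 matrix of 19059 genes and 24282 cells. The number at the end of a barcode tells 2 libraries apart, but no label ties it to a treatment, so the libraries are named by that number and set side by side. A ratio is library 2 over library 1 as a matter of order alone.

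Library 1 held 12337 cells with 203459556 UMIs, a median of 11695 UMIs and 4836 genes per cell, and a median mitochondrial share of 0.390%. Library 2 held 11945 cells with 185474400 UMIs, a median of 10756 UMIs and 4644 genes, and 0.585%. Cells with at least 200 genes, at least 500 UMIs and under 20% mitochondrial UMIs were kept, which removed 5 and 23 cells. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic thresholds marked 0 cells of library 1 and 2909 (24.4%) of library 2, so the cells with the highest scores were removed at the expected rate of 0.8% per 1000 cells instead: 1217 (9.87%) and 1137 (9.54%). That change followed a look at the doublet calls and preceded any gene or list result. It leaves 11115 and 10785 cells.

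Cells were scaled to 10000 UMIs and log-transformed, and 3000 variable genes gave 50 principal components, 15 nearest neighbors with shared-neighbor weights and Leiden clusters at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). A cluster took the class with the highest mean marker fold when at least 3 of its markers reached 20 CPM and a fold of 2. A second step was added after the first clusters were seen: clusters still without a name were scored against the mean of the named classes other than tumor cells, since a majority class shows no fold over all other cells. Fibroblasts were clustered again on 2000 variable genes and 30 components at resolution 0.5. Shares have exact Clopper-Pearson intervals. Tumor-cell background is the median over 9 epithelial markers of the class level over the tumor-cell level. That level and the tumor-cell RNA subtracted pool epithelial tumor cells with the unnamed cells, whose identity is undecided. Unnamed cells gave most UMIs of the pool, 106324496 against 50962076 in library 1 and 104199386 against 41675464 in library 2.

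UMIs were summed per class and library and scaled to the class total as CPM, with exact Poisson 95% intervals. Log2 ratios use CPM plus 1. A list needs at least 5 members with at least 20 CPM in 1 library. Its median log2 ratio is placed among 10000 random lists matched on expression in 20 bins, as a description of these libraries. With 1 library per treatment there is no replicate, and cells are not replicates, so no test, p-value or standard error is given. Lists, markers, the rules for naming genes and the first set of alternative settings were fixed before the data were examined. Single genes were named by rule: at least 50 CPM in 1 library, Poisson intervals that do not overlap, and at least 0.2 times the level of the class where the gene is highest. Of these, the 12 highest and 12 lowest log2 ratios in fibroblasts and the 5 highest and 5 lowest in other classes of at least 200 cells per library are named. List members with at least 20 CPM may also be named; those given as examples were picked after their values were seen. The call on intervals was checked on data simulated with 200 changed genes from the same Poisson model, so the check does not cover uneven counts between cells. In large classes intervals lay apart for most genes: of 5583 genes at 50 CPM in unnamed cells, 2264 were higher and 2254 lower in library 2. In fibroblasts 629 and 554 of 5047 were. Of 520 genes in the lists and markers, 6 are not in the probe set (Ccnb1, Eno1, Ly6c1, Ly6c2, Mx1 and Nos3).

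Alternatives were TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios factors, no filter on low genes, 0.1 or 10 CPM added, the mean of per-cell shares, cells thinned to 1000 UMIs, no cell filter, at least 1000 UMIs, no doublet removal, resolutions 0.5 and 2, and sub-cluster resolutions 0.3 and 0.8. Those added after the data were seen were automatic doublet thresholds, subtraction of tumor-cell RNA, the main fibroblast cluster alone, fibroblasts without the sub-clusters that carry markers of other classes, macrophages without the cluster above 5000 UMIs, genes without the 3 highest cells per library, shares of the named non-tumor cells, classes of at least 100 cells, and doublet and resolution settings outside fibroblasts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.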

Results

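Fibroblasts of the 2 pancreatic tumor libraries carried different programs. Genes of inflammatory cancer-associated fibroblasts (CAFs), which secrete cytokines and chemokines, stood higher in library 2, and several matrix genes of myofibroblastic CAFs, which lay down and contract the stroma, stood higher in library 1. Library 2 also held larger shares of T cells and dendritic cells, and more MHC class I RNA in tumor cells and in every other class compared. The series asks how blocking macropinocytosis, the bulk uptake of fluid and protein by cells, bears on CAF identity. The cell barcodes carry a library number that matches neither treatment label, so every value here is given for library 1 and library 2, with no treatment direction.

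T cells made up 1.02% of the cells of library 1 (113 of 11115, 95% interval 0.839 to 1.22) and 2.93% of those of library 2 (316 of 10785, 2.62 to 3.27), a ratio of 2.88. Dendritic cells, which present antigen to T cells, made up 0.333% (37 cells, 0.235 to 0.459) and 1.65% (178 cells, 1.42 to 1.91), a ratio of 4.96. Neutrophils stood at 1.24% and 1.69%, macrophages or monocytes at 7.0% and 7.16%, and blood endothelial cells at 1.17% and 1.07%. Fibroblasts were 3.33% (370 cells) and 4.10% (442 cells), a ratio of 1.23 that fell to 0.984 with automatic doublet thresholds. Epithelial tumor cells were 22.5% and 19.2%, a ratio of 0.852 that became 1.015 without doublet removal. Clusters without enough markers for a name held 62.6% and 61.6%. Among the named non-tumor cells alone (1659 and 2079), fibroblasts were 22.3% and 21.3% (ratio 0.953, 0.844 to 1.08), macrophages or monocytes 46.9% and 37.1% (0.792, 0.734 to 0.854) and blood endothelial cells 7.84% and 5.53% (0.706, 0.554 to 0.900). The ratio there was 2.23 for T cells, 3.84 for dendritic cells and 1.05 for neutrophils. Each library is 1 sample, so these intervals and those that follow cover counting error only, and no difference between animals can be tested.

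**Figure D1:**
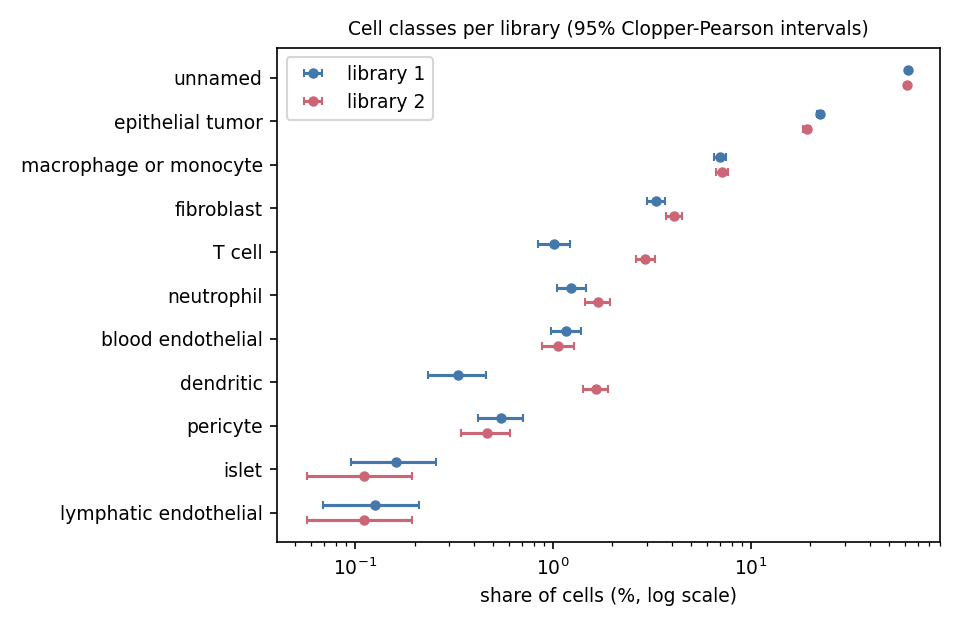
Share of cells of each class in library 1 and library 2, on a log axis, with exact 95% binomial intervals that cover counting error only.

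The inflammatory CAF list had a median log2 ratio (library 2 over library 1, CPM plus 1) of 0.78 in fibroblasts, above all 10000 random lists, with 10 of 12 members above 0. The chemokine Cxcl12, which guides leukocytes, stood at 37.4 and 114 CPM (log2 1.59). Dpt, a matrix protein of resting and inflammatory fibroblasts, stood at 12.1 and 36.5 CPM (1.52), Col14a1, a collagen of fibril surfaces, at 14.4 and 42.3 CPM (1.5), and the alarmin Il33 at 33.7 and 86.2 CPM (1.33). Few cells held the first 2: Dpt had a UMI in 18 and 37 cells, and Col14a1 in 27 and 49. In each library 3 cells held 43.8% and 45.8% of the Dpt UMIs. Without the 3 highest cells Dpt was at 1.43 and Col14a1 at 1.23. Complement C3 stood at 273 and 517 CPM (0.92). Lif, a cytokine of the same program, went the other way, at 118 and 52.8 CPM (-1.14). The list median was 0.50 without doublet removal. The Cxcl12 difference was absent in the main fibroblast cluster taken alone (log2 -0.003), so it came with the smaller of the 2 fibroblast clusters.

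The myofibroblastic CAF list had a median log2 ratio of -0.28, at percentile 0.27 of the random lists, and its members split. The surface protein Thy1 stood at 1403 and 477 CPM (-1.55), the fibril-associated collagen Col12a1 at 1578 and 559 CPM (-1.5), the growth-factor binder Igfbp3 at 5080 and 2098 CPM (-1.28) and the matrix protein Postn at 944 and 491 CPM (-0.94). The contractile genes Acta2 (246 and 380 CPM, 0.62), Tpm2 (613 and 738 CPM, 0.27) and Tagln (818 and 948 CPM, 0.21) were higher in library 2. The list median stayed below the random range in 12 of 14 alternatives, but was 0.002, within the range, without doublet removal. It was 0.58 with automatic doublet thresholds, which removed 0 cells of library 1 and 24.4% of library 2. Its direction thus depends on doublet handling, and the positive value rests on a filter that acted on 1 library. With those thresholds Thy1 was at -0.34, Col12a1 at -0.23, Igfbp3 at -0.27 and Postn at 0.20, against 1.62 for Acta2, 1.40 for Tagln (0.59 without doublet removal) and 0.38 for Tpm2. The antigen-presenting CAF list had a median of -0.24 and turned positive in 4 alternatives. H2-Aa, an MHC class II chain, stood at 110 and 50.4 CPM (-1.11), and at -0.49 without the highest cells. The acute-phase protein Saa3 (149 and 411 CPM, 1.46) and the secreted inhibitor Slpi (42.7 and 112 CPM, 1.36) were higher in library 2, but 3 cells held 54.5% and 82.3% of their library 1 UMIs. Without the 3 highest cells of each library Saa3 was at 2.17 and Slpi at 2.97, and without doublet removal Slpi was at 0.79.

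Among single fibroblast genes, the protease inhibitor Serpina3n stood at 39.0 and 161 CPM (log2 2.02), the calcitonin peptide gene Calca at 4.92 and 77.9 CPM (3.74), and the aminopeptidase Enpep at 9.45 and 62.1 CPM (2.59). Also higher were Tmeff2, a membrane protein with follistatin domains, at 10.2 and 54.7 CPM (2.31), the metalloprotease Adamts16 at 15.1 and 59.3 CPM (1.90) and the adhesion molecule Cdh2 at 15.9 and 56.9 CPM (1.78). Qrfp, a neuropeptide gene (log2 1.62), and Syt12, a synaptotagmin (1.55), also ranked here, at levels under those of pooled epithelial tumor and unnamed cells. That pool stood at 73.2 and 125 CPM for Qrfp and at 39.8 and 53.0 CPM for Syt12. Lower in library 2 were Abi3bp, a matrix-binding protein (113 and 16.7 CPM, -2.68), Hsd11b1, which activates glucocorticoids (122 and 21.3 CPM, -2.46), and Cyp26a1, which degrades retinoic acid (132 and 24.7 CPM, -2.37). So were the Hedgehog effector Gli1 (51.0 and 9.89 CPM, -2.26), Masp1 of the lectin pathway of complement (51.0 and 11.4 CPM, -2.07) and the vessel ligand Angpt4 (123 and 32.5 CPM, -1.89). The same held for the myofibroblast surface protein Lrrc15 (179 and 47.6 CPM, -1.89), the matrix protein Thbs4 (738 and 214 CPM, -1.78), the lipolysis inhibitor G0s2 (90.8 and 26.3 CPM, -1.75) and the proteoglycan Gpc3 (51.8 and 14.8 CPM, -1.74). Crabp1, a retinoic acid binder, stood at 81.7 and 11.7 CPM (-2.70), with 86.8% of its library 2 UMIs in 3 cells. With automatic doublet thresholds the lower genes kept their sign but shrank, Abi3bp to -1.50, Gli1 to -1.14, Lrrc15 to -0.57 and Thbs4 to -0.41. In the main fibroblast cluster alone Calca was at 1.15, Enpep at 1.44, Cdh2 at 0.87 and Syt12 at 0.91. Serpina3n was at 1.001 in thinned cells, and Qrfp at 0.38 without doublet removal and -0.19 with automatic thresholds. Immunoglobulin genes ranked highest but rest on single cells: 2631 of the 2948 Igkc UMIs, 227 of the 238 Jchain UMIs and 492 of the 495 Ighg1 UMIs of library 2 lay in the highest cell. The growth factor gene Igf2 (-2.93) had 91.1% of its library 1 UMIs in 3 cells and a log2 ratio of -1.31 without the highest cells.

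MHC class I genes were higher in library 2 fibroblasts, with a list median of 0.84 and 9 of 9 members above 0. H2-K1 stood at 348 and 734 CPM (1.08), H2-D1 at 60.9 and 128 CPM (1.06) and the peptide transporter Tap1 at 54.8 and 98.6 CPM (0.83). The hypoxia and glycolysis list had a median of -0.29, with 14 of 16 members below 0, among them Vegfa (581 and 450 CPM, -0.37, but -0.08 without the sub-clusters that carry tumor or myeloid markers) and Ndrg1 (160 and 110 CPM, -0.54). That median lay within the range of random lists in the main fibroblast cluster alone (-0.15) and in thinned cells (-0.25). It lay below that range in 12 of 14 alternatives, among them tumor-cell RNA subtracted (-0.48) and automatic doublet thresholds (-0.75). Genes of macropinocytosis and proton exchange had a median of 0.07, within the range of random lists. Fibrillar collagen genes had a median of 0.03 (0.34 without doublet removal, 1.001 with automatic doublet thresholds), with Col1a1 at 37350 and 39120 CPM. The proliferation list had a median of 0.59 that fell to 0.07 once tumor-cell RNA was subtracted. Markers of tumor cells in fibroblasts stood at 23.7% of their tumor-cell level in each library.

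**Figure D2:**
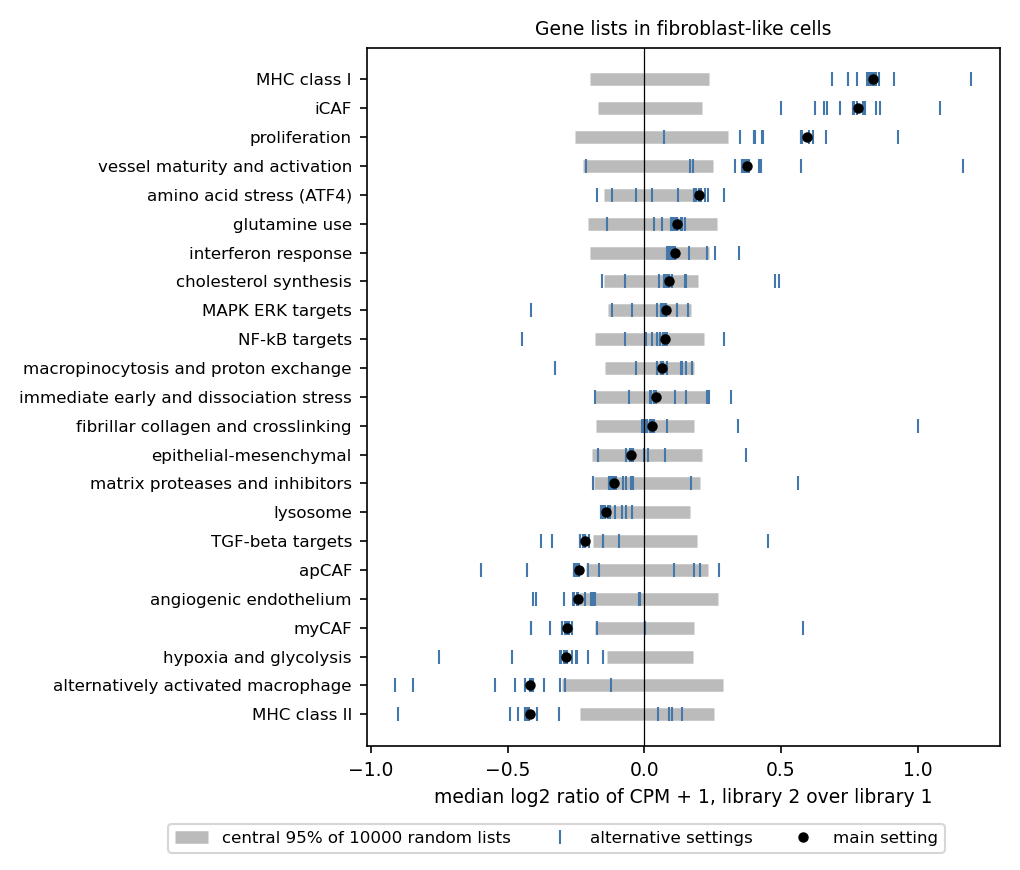
Median log2 ratio of each gene list in fibroblasts, library 2 over library 1, under the main setting (dots) and every alternative (ticks), with the central 95% of 10000 random lists matched on expression (bars).

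Fibroblasts fell into 7 sub-clusters whose shares differed between the libraries. Sub-cluster 1 held 47.0% of library 1 fibroblasts and 23.1% of those of library 2, sub-cluster 3 held 5.95% and 23.3%, and sub-cluster 4 held 6.49% and 21.0%. Lists were ranked over the 6 sub-clusters with at least 10 cells in each library, which leaves out sub-cluster 6 (17 and 7 cells). Among these, inflammatory CAF genes were highest in sub-cluster 3 in both libraries (mean log2 level per cell 0.513 and 0.537) and lowest in sub-cluster 5 (0.222 and 0.258). Myofibroblastic CAF genes averaged highest in sub-cluster 1 (2.55 and 2.43), although sub-cluster 5 led in library 1, and lowest in sub-cluster 4 (1.42 and 1.59). These ranks move with depth, which differs between sub-clusters (median 5760.5 UMIs in sub-cluster 1, 1809 in sub-cluster 4 and 1565.5 in sub-cluster 5). In cells thinned to 1000 UMIs sub-cluster 5 averaged highest in myofibroblastic genes (2.48 and 1.99, against 2.11 and 1.99 in sub-cluster 1). Sub-cluster 3 then averaged lowest (1.41 and 1.25), although it was last in neither library taken alone. In the same thinned cells sub-cluster 4 led in inflammatory genes in library 2. Antigen-presenting CAF genes were highest in sub-cluster 7 (1.68 and 1.43), a group of 24 cells that also carried myeloid markers, and fibrillar collagen genes in sub-cluster 5 (3.86 and 3.83).

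**Figure D3:**
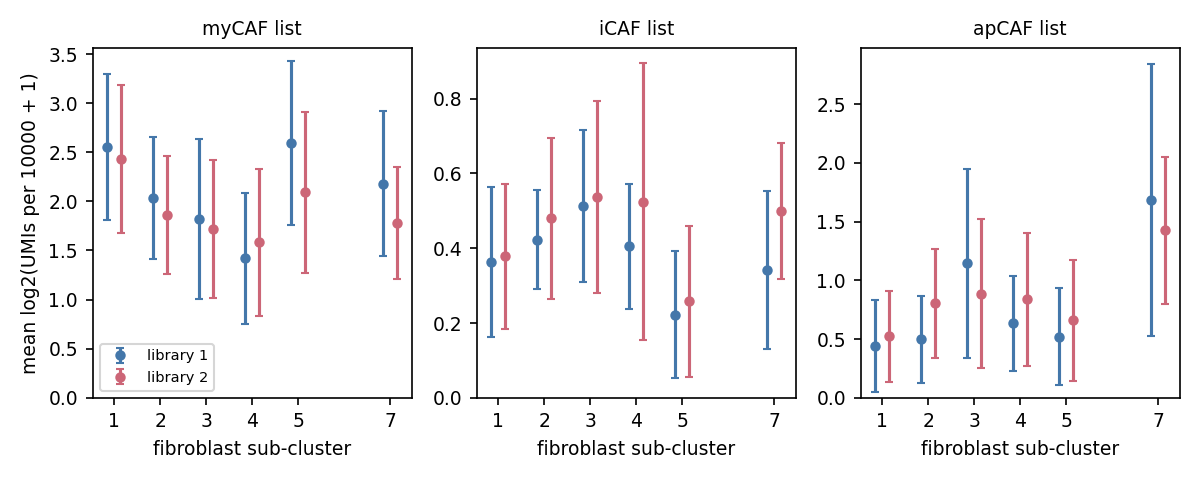
Mean level of the 3 CAF gene lists per fibroblast sub-cluster and library; bars are the SD between cells, and sub-clusters with under 10 cells in a library are not drawn.

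Tumor cells differed in antigen presentation. In epithelial tumor cells the MHC class II list had a median log2 ratio of 0.70 and the MHC class I list 0.56, with Cd74, the class II invariant chain, at 926 and 1576 CPM (0.77) and H2-K1 at 1057 and 1554 CPM (0.56). Interferon response genes had a median of 0.45, amino acid stress genes 0.17 (0.01 without doublet removal) and fibrillar collagen genes 0.38 (0.17 with no filter on low genes, 0.21 without doublet removal). The collagen genes stood low here, at a mean log2 level of 4.25 and 4.44 against 10.27 and 10.23 in fibroblasts. RNA carried over from fibroblasts was not tested. Immediate early genes, induced by signaling or tissue handling, had a median of -0.38, with Egr1 at 247 and 153 CPM (-0.68) and Fos at 339 and 218 CPM (-0.63). For the mean of per-cell shares these were -0.23, -0.44 and -0.34. The complement genes C1s1 (19.5 and 87.2 CPM, 2.10) and C3 (173 and 436 CPM, 1.33), the mitochondrial mt-Nd6 (1.11), the clock gene Per2 (1.02) and the brush-border gene Cdhr5 (0.96) were higher in library 2. For mt-Nd6 the pool of epithelial tumor and unnamed cells gave 1.09. The median mitochondrial share of all cells also differed, at 0.390% in library 1 and 0.585% in library 2. The matrix protease Mmp7 (116 and 23.4 CPM, -2.26), the antimicrobial lectin Reg3b (51.6 and 10.5 CPM, -2.19), the mucosal defense gene Bpifb1 (-1.72), the calcium binder Tesc (-1.18) and the immunoglobulin transporter Pigr (-1.18) were lower.

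Unnamed cells showed more cell-cycle, MHC class I and cholesterol synthesis RNA in library 2. The proliferation list had a median of 1.33 (0.77 without doublet removal) with 14 of 14 members above 0. The replication enzyme Top2a stood at 31.9 and 100 CPM (1.62), and Cdk1, the mitotic kinase, at 16.5 and 54.6 CPM (1.67). Hist1h1b (2.00), Pimreg (1.76) and Hist1h2ap (1.75) were the other cell-cycle genes ranked highest. Without doublet removal Cdk1 was at 1.10, Hist1h1b at 1.33 and Hist1h2ap at 1.09. MHC class I genes had a median of 1.24, with H2-K1 at 220 and 689 CPM (1.64), and cholesterol synthesis genes 0.56, with 13 of 13 members above 0. The gel-forming mucins Muc5b (292 and 66.0 CPM, -2.13) and Muc5ac (115 and 28.0 CPM, -2.0), the guidance gene Sema5a (-1.10), the glycosyltransferase Galnt7 (-1.10) and the mucosal peptide Tff1 (-1.06) were lower. Weighting library 2 to the cluster shares of library 1 took the per-cell proliferation median from 1.03 to 0.19, the cholesterol median from 0.44 to 0.13 and the MHC class I median from 1.32 to 0.84.

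Macrophages or monocytes carried more MHC class I RNA in library 2, with a list median of 0.86, H2-K1 at 782 and 1543 CPM (0.98) and H2-D1 at 137 and 282 CPM (1.03). Without the macrophage cluster of highest UMI count these were 0.51, 0.63 and 0.67, and the median was 0.56 for the mean of per-cell shares and 1.62 with automatic doublet thresholds. Targets of MAPK signaling had a median of -0.47, among them the receptor Epha2 (-0.89). The median was -0.04 without doublet removal, -0.98 with tumor-cell RNA subtracted and -1.39 with automatic doublet thresholds (Epha2 -0.28, -2.82 and -1.90). MHC class II, interferon and lysosome lists had medians of 0.58, 0.47 and 0.37, which became 0.05, 0.001 and 0.08 without that cluster and 1.71, 1.26 and 0.58 with automatic doublet thresholds. The protease gene Ctsk (11.6 and 296 CPM, 4.56), the chemokine genes Ccl17 (67.8 and 447 CPM, 2.70) and Ccl22 (9.07 and 66.4 CPM, 2.74), the protease gene Mmp9 (79.2 and 495 CPM, 2.63) and the lectin gene Fcna (11.6 and 56.1 CPM, 2.18) ranked highest. Few cells carry them, and in library 2 Ccl17 and Ccl22 stood highest in dendritic cells and Mmp9 in neutrophils. Ctsk had a UMI in 5.78% and 4.92% of macrophages (median 3345 and 2750 UMIs), under the 9.56% and 9.19% of unnamed cells (median 11955 and 11764.5 UMIs). Ccl22 had a log2 ratio of 0.93 without the highest cells, and at the finer clustering Ctsk was at 0.10 and Mmp9 at -0.75. The genes ranked lowest were Ivl (-1.69), Mmp3 (-1.66), Nr1d1 (-1.48), Mcpt8 (-1.41) and Egflam (-1.34). All stood higher in the pool of epithelial tumor and unnamed cells than in macrophages. Tumor-cell markers in macrophages were at 42.3% and 33.8% of their level in that pool.

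T cells of library 2 carried more regulatory T cell RNA, with a list median of 1.26 (0.67 without doublet removal, 2.499 with automatic doublet thresholds) and 7 of 7 members above 0. Markers of tumor cells in T cells stood at 49.8% and 46.7% of their tumor-cell level. Foxp3, the regulatory lineage factor, stood at 9.40 and 62.5 CPM (2.61, all 9 UMIs of library 1 in 3 cells), the inhibitory receptor Ctla4 at 27.2 and 80.2 CPM (1.53, but 0.56 without doublet removal), the chemokine receptor Ccr8 at 30.3 and 83.8 CPM (1.44) and the checkpoint receptor Lag3 at 238 and 548 CPM (1.20, but 0.56 for the mean of per-cell shares). The cytotoxicity list had a median of -0.50, but 0.87 with automatic doublet thresholds. The granzyme gene Gzmb (-1.74) became -0.23 and the perforin gene Prf1 (-1.81) became 0.47 without the 3 highest cells of each library, and the granzyme gene Gzmk went from -1.85 to -1.96, but to -0.68 with automatic doublet thresholds. Blood endothelial cells had a proliferation median of 1.75, with Top2a at 2.11 and Cdk1 at 2.75. That median was 0.89 for the mean of per-cell shares, 0.93 without doublet removal and 1.07 with automatic doublet thresholds. Few endothelial cells held these genes: Top2a had a UMI in 10 and 21 cells, and Cdk1 in 9 and 17. Neutrophils had medians of 1.31 for MHC class I (0.22 for the mean of per-cell shares) and 1.45 for MHC class II, with tumor-cell markers at 47.3% and 65.0% of the tumor-cell level. These 3 classes hold 113 to 316 cells per library and were added after the data were seen.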

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

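The alternatives with automatic doublet thresholds, tumor-cell RNA subtracted, the main fibroblast cluster alone, the mixed sub-clusters left out, the high-UMI macrophage cluster left out and the highest cells left out, shares of the named non-tumor cells, and all doublet and resolution settings outside fibroblasts, were chosen after the results were seen. Inflammatory CAF genes stayed above the range of random lists in 14 of 14 alternatives (0.501 without doublet removal to 1.083 with automatic thresholds), and MHC class I genes in fibroblasts likewise (0.688 to 1.195). The share ratio of T cells ranged from 2.23 to 3.03 and that of dendritic cells from 3.84 to 5.06. As shares of the named non-tumor cells the ratios were 0.7918 for macrophages, 0.9533 for fibroblasts, 2.232 for T cells, 1.052 for neutrophils and 0.7059 for endothelial cells. Of 1101 list medians under an alternative, 24 had the sign opposite to a main median that lay outside the random range. Sign changes of medians within that range were not counted. Of 1257 gene ratios, 10 changed sign. Changes of over 1.5 times, in either direction, were found under at least 1 alternative for 70 of 99 gene ratios and for 44 of 53 list medians outside the random range. The cause was not tested for any change listed here, except where a few cells are named.

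Doublet handling moved the most. Without doublet removal the share ratio was 1.015 for epithelial tumor cells and 0.9101 for unnamed cells. The medians in fibroblasts were 0.002 for myofibroblastic, 0.108 for antigen-presenting and 0.103 for MHC class II genes (main setting -0.419). MAPK targets in epithelial tumor cells were at 0.018 (main setting -0.102). Angiogenic genes in endothelial cells were at 0.064 (main setting -0.294), and collagen genes in neutrophils at 0.055. Igkc was -0.445 and Jchain -0.402 in fibroblasts, and 1 sub-cluster led in myofibroblastic genes in 2 libraries, against 1. Automatic thresholds removed cells of library 2 alone. With them the share ratio was 0.8631 for macrophages, 0.9844 for fibroblasts, 0.5612 for endothelial and 1.03 for unnamed cells. Medians in fibroblasts were then 0.579 for myofibroblastic and -0.597 for antigen-presenting genes. They were 0.451 for TGF-beta (main setting -0.218), -0.172 for ATF4 (main setting 0.199) and -0.213 for vessel genes (main setting 0.377). Cytotoxicity in T cells was 0.865, collagen genes in T cells -0.207 and angiogenic genes in endothelial cells 0.808. Igkc was -5.662, Jchain -4.052, Qrfp -0.185 and Postn 0.197.

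With the mean of per-cell shares the fibroblast medians were -0.416 for myofibroblastic, 0.273 for antigen-presenting, -0.032 for ATF4 and 0.138 for MHC class II genes. NF-kB targets in macrophages were then at -0.001 (main setting 0.195), inhibitory receptors in T cells at -0.092 (main setting 0.464) and Col1a1 in fibroblasts at -0.008. With thinned cells the medians were -0.413, 0.205, -0.117 and 0.05 for the same 4 fibroblast lists. Sub-cluster 3 then led in inflammatory genes in 1 library, against 2. Without the mixed sub-clusters antigen-presenting genes were at 0.18 and MHC class II genes at 0.092. With tumor-cell RNA subtracted antigen-presenting genes were at -0.428. The main fibroblast cluster alone gave -0.173 for myofibroblastic genes and -0.003 for Cxcl12. Without a cell filter the share ratio was 0.7842 for epithelial and 1.009 for unnamed cells, and with at least 1000 UMIs it was 0.9383 for epithelial cells. With no filter on low genes epithelial-mesenchymal genes in unnamed cells were at 0.002 (main setting -0.2). At resolution 2 Mmp9 in macrophages was -0.749, and without the 3 highest cells Prf1 in T cells was 0.473, since those cells held 86.8% of its library 1 UMIs. At sub-cluster resolution 0.8 the lead in myofibroblastic genes held in 2 libraries, and at 0.3 that in antigen-presenting genes in 1. No paired analysis was possible because each treatment has 1 library.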

Other observations

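Every test of an explanation in this part was chosen after the result it measures had been seen. Of the alternatives given for immune and endothelial cells, those on normalization, low genes, the added CPM and per-cell shares were planned, and those on doublets, resolution and subtraction were chosen after the data were seen. Fibrillar collagen genes had a median log2 ratio of 0.996 in macrophages, which was 0.381 for the mean of per-cell shares, 0.558 without doublet removal and 0.338, within the random range, with automatic doublet thresholds. It was 0.873 in T cells (-0.207, within the range, with automatic thresholds) and -0.622 in neutrophils (0.055, within the range, without doublet removal). These collagen levels were low, with a mean log2 level of 4.79 and 5.60 in macrophages, 4.76 and 5.64 in T cells and 5.44 and 4.99 in neutrophils. Fibroblasts stood at 10.27 and 10.23. RNA carried over from fibroblasts was not tested, so the ratios may not be of these cells. Naive and memory T cell genes had a median of 1.40 in T cells (0.854 to 1.715 in 9 alternatives), with the cytokine receptor Il7r at 27.2 and 73.1 CPM, a log2 ratio of 1.40 that was 0.546 for the mean of per-cell shares. Pericytes numbered 61 and 50, islet cells 18 and 12 and lymphatic endothelial cells 14 and 12 in libraries 1 and 2.

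Several clusters came mostly from 1 library and may be a property of that library and not a cell type. Cluster 24 held 269 and 4 cells, cluster 15 held 28 and 571, cluster 8 held 85 and 931, and cluster 9, which carried cell-cycle genes, 194 and 771. Cell-cycle RNA was not confined to cluster 9, since Top2a had a UMI in 1139 and 2010 unnamed cells. Giving library 2 the cluster shares of library 1 left the MHC class I median of unnamed cells at 0.843.

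Inflammatory CAF genes were higher in library 2 fibroblasts. Tumor-cell RNA at the median marker share does not account for this, since the median was 0.863 after subtraction of the pooled tumor and unnamed profile. It was 0.657 without sub-clusters 2 and 7, which carry tumor or myeloid markers. Both values, with their counting intervals (0.371 to 0.949 and 0.493 to 0.774), lie above the random range. The lowest marker share subtracted in library 1 and the highest in library 2 raised the median (1.028, 0.681 to 1.125). The opposite pairing was not run, so this was no harder check. Merged cells are not excluded, since sub-cluster 4 was kept. Its Krt8 (1137 CPM) exceeded that of sub-cluster 2 (938 CPM), although its Krt18 (407 CPM) did not (746 CPM). It held 6.49% and 21.0% of the fibroblasts of libraries 1 and 2. At sub-cluster resolution 0.8 a group of 23 and 73 cells had several mitochondrial genes among its leading genes. Its median was 1540.5 UMIs, with Col1a1 at 11680 CPM and Krt8 at 1514 CPM. Overlap of that group with sub-cluster 4 was not measured. Different shares of fibroblast states remain open. Weighting library 2 to the sub-cluster shares of library 1 took the per-cell median from 0.668 to 0.168, but those sub-clusters were made partly from the list's own genes. A second weighting, added after that value was seen and using sub-clusters made without the CAF list genes, gave 0.673. The first is circular and the second may have lost the states in question, so the explanation cannot be told apart from a change within states, and no biological explanation was tested because the libraries have no known treatment.

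MHC class I genes were higher in library 2 in every class with a list value, although the mean of per-cell shares gave 0.223 in neutrophils and 0.284 in T cells, both within the random range, and endothelial cells were within it in 4 of 10 alternatives. Tumor-cell RNA carried over at the median marker share does not account for this in macrophages and fibroblasts. The median there was 0.726 and 0.779 after subtraction, and its counting interval stayed above the random range. With the lowest marker share subtracted in library 1 and the highest in library 2 the median rose to 1.003 and 0.832. The opposite pairing was not run, so these outer shares were no harder check. In neutrophils tumor-cell markers stood at 47.3% and 65.0% of the tumor-cell level. The median there was 1.817 (1.076 to 2.238) after subtraction, above the random range, but with those outer shares its interval (0.88 to 2.623) reached into that range (up to 1.537). Subtraction changed the median little in T cells, from 0.692 (0.502 to 0.789) to 0.594 (0.396 to 0.7), and in endothelial cells, from 0.362 (0.19 to 0.622) to 0.342 (0.159 to 0.617). The upper end of the random range rose from 0.236 to 0.464 and from 0.301 to 0.356, which ended the call in endothelial cells and placed that of T cells within counting error. With the outer shares the T cell median was 1.317 (1.153 to 1.448), above a random range that ends at 1.104, and the endothelial one 0.484 (0.272 to 0.748), whose interval reaches into a range that ends at 0.376. In these 3 classes carried RNA cannot be told apart from a difference of the cells themselves, since the counts are few, although subtraction did not remove the folds. Different shares of the unnamed clusters leave most of the difference in unnamed cells, with 0.843 of 1.322 kept after weighting, and 15 of 17 unnamed or epithelial clusters lay above 0 (-0.006 to 1.67). No biological explanation was tested, and a difference between the library preparations stays open.

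Unnamed cells were the majority. Droplets with free RNA alone do not account for them as a whole, since their median UMI count was 3.45 and 3.97 times that of named non-tumor cells, whose droplets hold free RNA as well. Of the 14 unnamed clusters, 2 (629 cells) had a median under that of named non-tumor cells in at least 1 library and stay open. The unnamed cells could be tumor cells with little Epcam: 58.9% of them (8010 of 13598) lie in 6 clusters whose Krt8 and Krt18 exceed every non-tumor class of at least 100 cells and whose Epcam lies under every named epithelial cluster, in both libraries. With the 30 islet cells counted as a class, 4 of these clusters and 34.0% of the cells (4624) are left. Islet cells themselves held tumor-cell markers at 86.6% and 89.4% of the pooled level, so clusters under their keratins may still be tumor cells. The leukocyte gene Ptprc stood at 437 and 282 CPM in cluster 28, and at most at 13.5 CPM in other unnamed clusters. Their Col1a1 was at most 219 CPM, against at least 22930 CPM in each fibroblast sub-cluster. These values argue against leukocytes or fibroblasts as the bulk of those clusters, but the explanation by little Epcam stays undecided. Little Epcam does not describe unnamed clusters 17 (642 and 611 CPM), 5 (228 and 209 CPM) and 28 (322 and 226 CPM), or cluster 20 in library 2 (176 CPM), against 176 and 161 CPM in the lowest epithelial clusters. No biological explanation was tested.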
